A study of Mus musculus with 22 samples.

How the data were processed

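Gene expression was measured on 22 Illumina mouse bead arrays, hybridised with biotin-labelled cRNA from colon epithelial cells. The mice were BALB/c, 6 to 10 weeks old and labelled male. They were either wild type (WT) or deficient in the polymeric immunoglobulin receptor (pIgR-KO, here KO), and either untreated or given antibiotics for 17 days. The antibiotics are not given in the sources used here, nor is whether an array held the RNA of 1 mouse or of several. Per the labels, the colon was opened, cut into pieces and shaken in 20 mM EDTA for 25 min to release the epithelium, with no sorting step named. The 4 groups were WT_untreated (5 arrays), WT_antibiotic (5 arrays), KO_untreated (6 arrays) and KO_antibiotic (6 arrays), as the labels give them. Arrays are named by group and replicate number.

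The deposited scanner table holds 45281 probes. Per the file headers, its first kind of column is the mean bead signal of each probe, an intensity on a linear scale with no value below 0 and no background subtracted. Its second kind of column is, per the file headers, a detection p-value for each probe and array. The software version, image processing and treatment of outlying beads are not given in the sources used here. The authors' processed table holds an intensity per probe on a linear scale. Its 22 columns hold the same sorted values, so quantile normalisation between arrays was read from the values, and the median of every column was 52.0. Each of its columns ranked the probes as the scanner signal of that array did, which settled scale and direction, and it was used only as an alternative.

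Background was corrected and arrays were quantile normalised with neqc in limma 3.58.1 (R 4.3.3), which estimates the background from the detection p-values and adds an offset of 16 before log2. Probes with a detection p-value under 0.05 on at least 5 arrays were tested, 19993 in all. Between 15975 and 18388 probes were detected per array. All 22 arrays entered 1 limma fit (lmFit, eBayes) with a mean per group, and 5 contrasts were tested two-sided: KO against WT without and with antibiotics, antibiotic against untreated in WT and in KO, and the difference between the antibiotic effects of the genotypes (the interaction). Adjusted p-values are Benjamini-Hochberg values over all tested probes, with a threshold of 0.05. The p-values measure the spread between these samples. The number of arrays limits the precision: the median standard error of a log2 difference was 0.177 for both KO contrasts, 0.184 and 0.168 for the antibiotic contrasts in WT and KO, and 0.250 for the interaction.

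Probe names came from the platform annotation and were updated to the reference gene table of assembly GRCm38.p6. Of the probes, 34885 had 1 symbol, 18 had several and 10378 had none, and probes with several or none stayed unnamed. Through the gene identifier 34807 probes matched the reference and through an accession 11, while 67 kept a symbol that the reference does not hold. The files name no genome build, so no coordinates are given, and the reference served only for names and for the order of genes along chromosomes. A gene was represented by its tested probe with the highest mean log2 level, which gave 10705 genes. A probe not detected on any array of a group has only a bound there. The fold is then written as at least the value obtained against the lowest signal among detected probes of each array, or the probe's own value where that was higher.

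The groups, contrasts, test, filter, the rule for named genes, 28 gene lists and the alternatives listed first in this paragraph were fixed before the data were examined. The named genes are, per contrast, the 10 with the largest rise and the 10 with the largest fall among genes past the threshold, up to 4 members per gene list with the smallest p, and Pigr. Predicted genes and numbered clones were passed over. Where fewer than 5 genes passed, the 10 with the smallest p were named as not past the threshold. The fixed alternatives were no background correction, median scaling in place of quantile normalisation, the authors' values, no filter and a stricter filter (detection p under 0.01, 13913 probes), array weights, the replicate number as a block, a leukocyte marker score as a covariate, only the groups compared, probes averaged per gene, and each array left out in turn. Median scaling over detected probes, the number of detected probes as a covariate, the fit without KO_antibiotic 3 and 4, and KO_untreated represented by the 1 array whose description lacks a suffix were chosen after seeing the data. Median scaling, where nothing else is said, used the median over all 45281 probes. At most 18388 of them were detected on an array, so that median lies among undetected probes. Slide as a block was planned but not run, since the files name no slides.

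The 28 lists hold 772 members, 721 of them with a named probe. Each was tested with camera, which compares a list with the other genes, with its preset correlation of 0.01 and again with a correlation estimated from the data, and with fry, which asks only whether the list moves on balance. List p-values were adjusted over the 28 lists per contrast. Members past the threshold are counted over all probes tested and, in those words, adjusted over the list alone. Genes near Pigr, 100 neighbours on each side, were compared with all other tested genes by a two-sided Fisher exact test. For the counts of probes, 100 splits of the same arrays into groups of the same sizes, the real one included, were drawn with a fixed seed and fitted. For the interaction, the residuals of an additive fit of genotype and treatment were dealt to the arrays instead, a test that replaced splits of the treatment labels within genotype after their result was seen. Another 4 lists (Paneth cell, ileal enterocyte, pancreatic acinar and type 2 response genes) were written after the results were seen and serve only the closing section. There the ileal and pancreatic markers, with Clps, Pnliprp1 and Pnliprp2 added, were compared by group medians, and those below the median tested probe in WT_untreated are called dim. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

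The procedure was tested on simulated data with the means and spread of the 19993 probes and 200 changed probes. Of probes changed 2-fold, 83.6% were recovered for KO against WT untreated, 82.1% for the same contrast with antibiotics, 61.2% for antibiotic in WT, 88.1% for antibiotic in KO and 38.8% for the interaction. Of probes changed 1.5-fold, 31.3%, 40.3%, 23.9%, 29.9% and 8.96% were recovered, in the same order. Among the calls, 3.40%, 3.27%, 3.20%, 7.74% and 5.21% were false. A simulated list of 20 genes shifted by 0.5 log2 units gave an adjusted p of 5.01e-19 by camera, and 0 of 27 unshifted lists passed. Probes and genes were drawn independently of each other, so the simulation could not show false calls of lists whose genes move together. In the data the estimated correlation was 0.677 for MHC class II genes.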

Results

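The data are 22 arrays of epithelial cells released from the mouse colon, where the polymeric immunoglobulin receptor carries secretory antibodies across the epithelium into the gut. WT and KO mice, the latter lacking this receptor, were left untreated or given antibiotics, with 5 WT_untreated, 5 WT_antibiotic, 6 KO_untreated and 6 KO_antibiotic arrays. On average 17833, 17479, 17360 and 17284 probes were detected per array in the WT_untreated, WT_antibiotic, KO_untreated and KO_antibiotic groups. The series title names mucosal homeostasis without secretory antibodies, and the groups ask how the loss of the receptor altered the epithelium with and without antibiotics. All differences are log2 values from limma with their standard error (SE), and a gene that rose or fell had an adjusted p under 0.05.

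Pigr, the gene that was disrupted, was measured by 1 probe (ILMN_1225605) and was lower in the KO mice under both treatments. Its log2 level was 11.85 ± 0.37 (SD, n = 5) in WT_untreated, 11.55 ± 0.27 (SD, n = 5) in WT_antibiotic, 9.99 ± 0.74 (SD, n = 6) in KO_untreated and 9.34 ± 0.60 (SD, n = 6) in KO_antibiotic. Pigr was 3.62-fold lower in KO mice without antibiotics (log2 -1.86, SE 0.30, adjusted p = 0.00131) and 4.60-fold lower with them (log2 -2.20, SE 0.30, adjusted p = 0.000654). The highest KO level was 10.73 and the lowest WT level 11.32, so every KO array lay below every WT array. The probe was detected on all 22 arrays, and its place relative to the disrupted part of the gene is not given in the sources used here, so the remaining signal does not measure remaining receptor. Antibiotics changed Pigr past the threshold neither in WT (adjusted p = 0.645) nor in KO mice (adjusted p = 0.158), and the difference between these effects was -0.35 (adjusted p = 0.799). With median scaling the difference with antibiotics was -2.04 and no longer passed (adjusted p = 0.154).

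**Figure D1:**
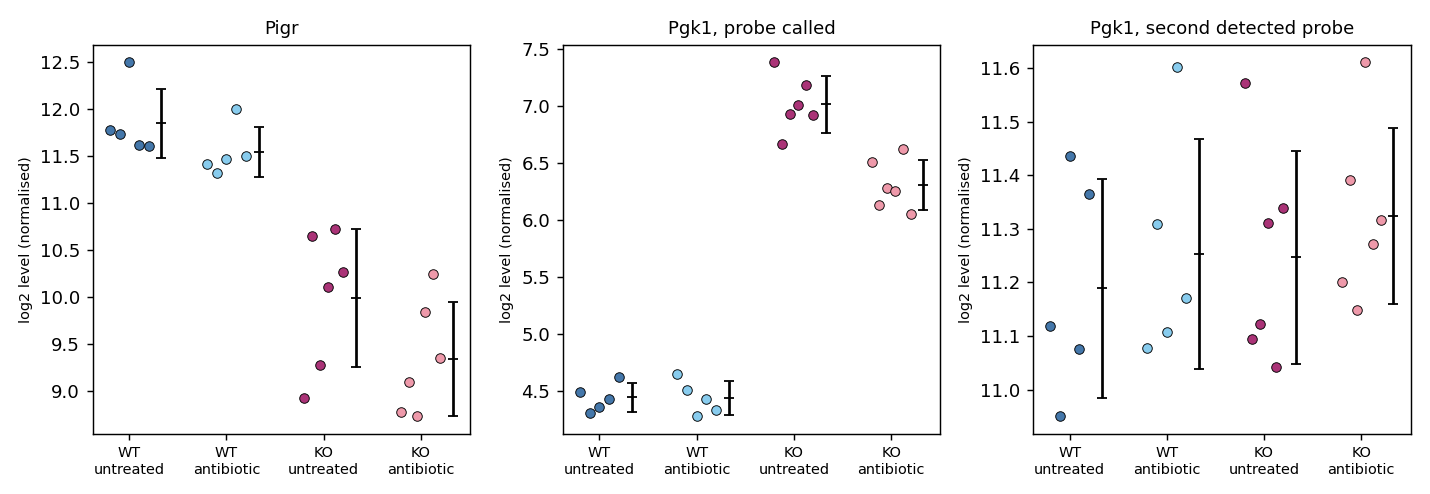
Log2 level per array (y axis) of Pigr, of the Pgk1 probe that differed between genotypes and of the second detected Pgk1 probe in the 4 groups (x axis), with points for arrays and bars for the mean and SD. The lowest WT level of Pigr was 11.32 and the highest KO level 10.73.

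The first comparison asks what the loss of the receptor changed in untreated mice. In the colon epithelium of KO mice, Mcpt1, Cma2, Defa3 and Reg4 rose, and Sult1d1 and Ugt8a fell (n = 6 KO and 5 WT arrays). Mcpt1, a protease of mucosal mast cells, was 8.21-fold higher (log2 3.04, SE 0.61, adjusted p = 0.00536), and the chymase gene Cma2 6.89-fold (log2 2.78, SE 0.44, adjusted p = 0.000916). Defa3, which encodes a defensin of Paneth cells, rose 6.12-fold (log2 2.61, SE 0.35, adjusted p = 0.000223) and Reg4, which encodes a secreted lectin, 5.73-fold (log2 2.52, SE 0.49, adjusted p = 0.00486). The sulfotransferase gene Sult1d1 was 5.00-fold lower (log2 -2.32, SE 0.29, adjusted p = 9.06e-05) and Ugt8a, a glycosyltransferase gene of galactolipid synthesis, 3.70-fold (log2 -1.89, SE 0.31, adjusted p = 0.00131).

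Among the other genes with the largest rises were Pnliprp2, a pancreatic lipase-related gene (12.7-fold, adjusted p = 0.0156), the secreted phospholipase gene Pla2g2a (5.70-fold, adjusted p = 0.00536) and the DNA damage checkpoint gene Rad9a (5.45-fold, adjusted p = 0.00209). The monoamine transporter gene Slc29a4 (5.11-fold, adjusted p = 0.000333), the defensin gene Defa20 (at least 3.88-fold, adjusted p = 0.00016) and Clps, the gene of the lipase cofactor colipase (4.68-fold, adjusted p = 0.0249), rose too. Among the other large falls were Usp53 (3.44-fold, adjusted p = 0.0103), Zfp97 (3.31-fold, adjusted p = 0.00264), the aldo-keto reductase gene Akr1c19 (3.26-fold, adjusted p = 0.00492) and the antimicrobial lectin gene Reg3a (3.24-fold, adjusted p = 0.0262). Lower were also the ubiquitin ligase gene Marchf7 (3.13-fold, adjusted p = 0.00075) and Sh3bgrl (3.08-fold, adjusted p = 0.00536). Zranb2 fell by 1.58 on the log2 scale (adjusted p = 0.0151). Each of these genes lay on the same side of the WT mean on 6 of 6 KO arrays. Beyond all WT arrays lay 1 of 6 KO arrays for Reg3a, 2 for Pla2g2a, 3 for Clps and 5 for Pnliprp2 and Rad9a. For the other genes in this paragraph it was 6 of 6. The call of Pnliprp2 was lost without WT_untreated 5 (adjusted p = 0.0508). That of Clps was lost without KO_untreated 1 or WT_untreated 1, 2 or 5 (highest adjusted p 0.0676). That of Reg3a was lost without KO_untreated 4 or 5 or WT_untreated 1, 2 or 4 (highest adjusted p 0.0732).

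**Figure D2:**
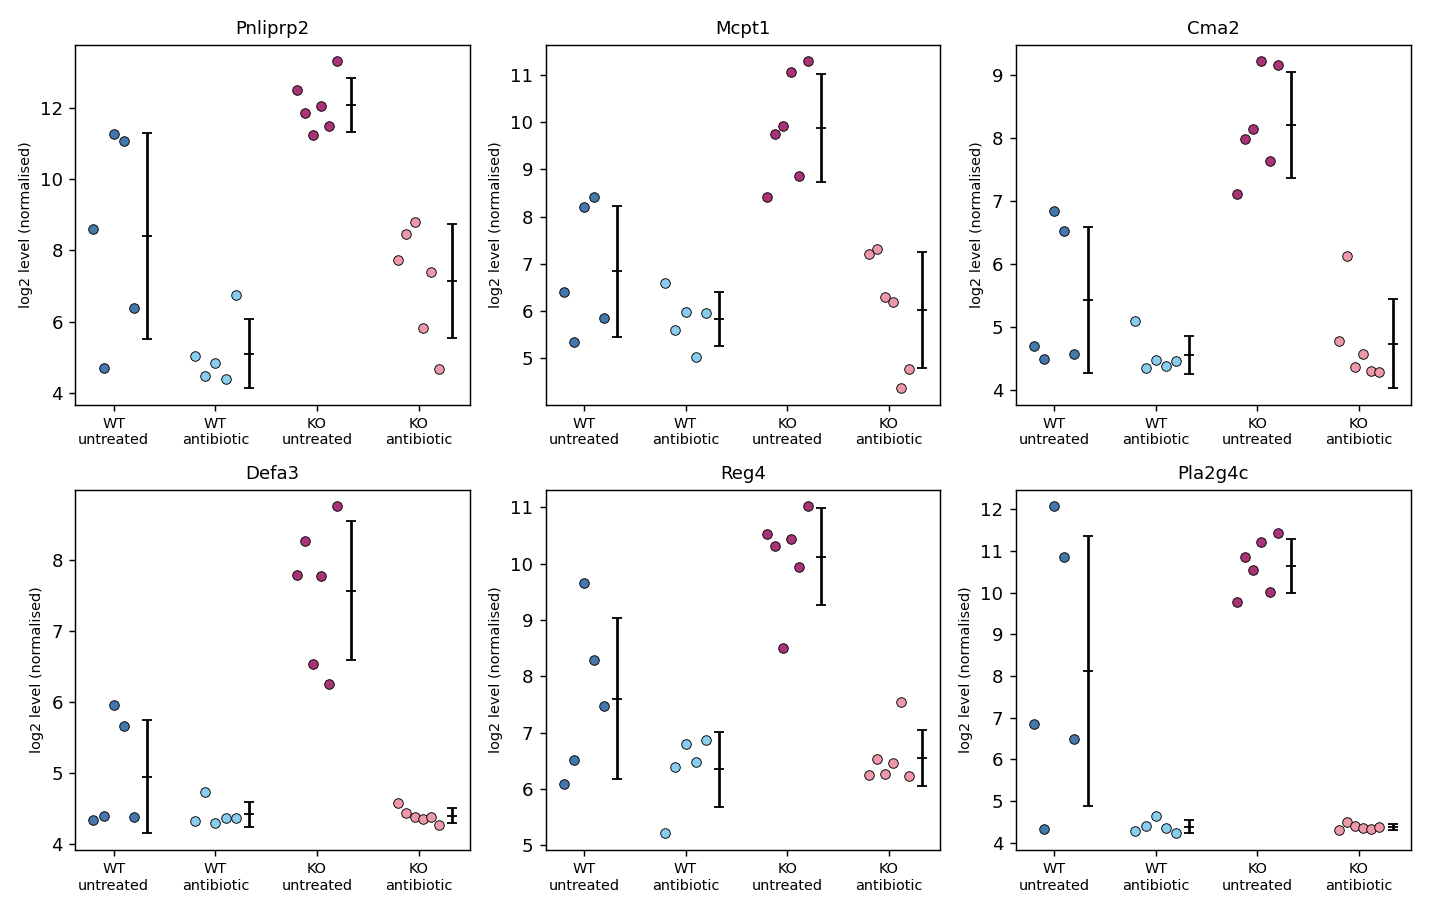
Log2 level per array (y axis) of Pnliprp2, Mcpt1, Cma2, Defa3, Reg4 and Pla2g4c in the 4 groups (x axis), with points for arrays and bars for the mean and SD. Of the untreated arrays, 6 of 6 KO arrays lay above all WT arrays for Mcpt1, Cma2 and Defa3, and 5 of 6 for Pnliprp2 and Reg4.

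Genes of sterol synthesis, tuft and goblet cells, protein folding and cell division stood higher in untreated KO mice by camera with the preset correlation. Of the 9 lists past the threshold in this comparison, 0 passed with an estimated correlation. For the counts of members below, 10.9% of all tested probes were called, 1110 higher and 1070 lower of 19993. Of 18 cholesterol synthesis genes, 8 rose (10 adjusted over the list alone, median 0.54, camera adjusted p = 6.68e-05, 0.182 as the adjusted p with an estimated correlation). They included the farnesyl diphosphate synthase gene Fdps (log2 1.02, SE 0.17, adjusted p = 0.00136) and Srebf2, which encodes the transcription factor of the pathway (log2 0.96, SE 0.16, adjusted p = 0.00163). Of 13 tuft cell markers, 8 rose (8 adjusted over the list alone, median 0.73, adjusted p = 6.13e-05, estimated-correlation adjusted p = 0.269). They included Avil (2.95-fold, adjusted p = 0.000333), Alox5ap of leukotriene synthesis (log2 1.34, SE 0.24, adjusted p = 0.0029) and the taste channel gene Trpm5 (log2 1.09, SE 0.25, adjusted p = 0.0118). Goblet cell markers rose in 7 of 19 cases (8 adjusted over the list alone, median 0.35, adjusted p = 0.000439, estimated-correlation adjusted p = 0.306). They included Spink4 (2.46-fold, adjusted p = 0.00807) and the transcription factor gene Foxa3 (log2 0.71, SE 0.16, adjusted p = 0.0112). In the unfolded protein response list 8 of 23 rose (13 higher and 1 lower adjusted over the list alone, median 0.41, adjusted p = 6.13e-05, estimated-correlation adjusted p = 0.182). They included the asparagine synthetase gene Asns (log2 0.88, SE 0.17, adjusted p = 0.00389) and Sdf2l1 (log2 1.26, SE 0.23, adjusted p = 0.00296). Of 32 cell cycle genes 4 rose (6 adjusted over the list alone, median 0.37, adjusted p = 0.00139, estimated-correlation adjusted p = 0.63), Mcm2 of the replicative helicase among them (log2 0.82, SE 0.20, adjusted p = 0.0161). Oxidase and acute phase genes rose in 4 of 14 cases (8 adjusted over the list alone, median 0.68, adjusted p = 0.000338, estimated-correlation adjusted p = 0.182), with Duoxa2, the maturation factor of an epithelial peroxide-producing oxidase, 3.50-fold higher (adjusted p = 0.00173) and Lbp, which encodes a lipopolysaccharide-binding protein, 0.80 (SE 0.19, adjusted p = 0.0142).

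Xenobiotic metabolism, fatty acid oxidation and surface colonocyte genes stood lower by camera with the preset correlation, but not with an estimated one. Of 32 xenobiotic metabolism genes 8 fell (9 adjusted over the list alone, median -0.25, adjusted p = 9.06e-05, estimated-correlation adjusted p = 0.314). They included the phenol sulfotransferase gene Sult1a1 (log2 -1.15, SE 0.16, adjusted p = 0.000333) and the glucuronosyltransferase gene Ugt2b34 (log2 -1.28, SE 0.27, adjusted p = 0.00753). Of 31 fatty acid oxidation and ketogenesis genes 5 fell (1 higher and 7 lower adjusted over the list alone, median -0.26, adjusted p = 0.0026, estimated-correlation adjusted p = 0.389). Ppargc1a, a coactivator gene of mitochondrial metabolism, was among them (log2 -1.05, SE 0.30, adjusted p = 0.0275), and its call was lost without KO_untreated 1 or WT_untreated 1, 2 or 5 (highest adjusted p 0.069). Surface colonocyte markers included 1 higher and 2 lower of 30 (1 higher and 3 lower adjusted over the list alone, median -0.27, adjusted p = 0.00477, estimated-correlation adjusted p = 0.182). The magnesium channel gene Trpm6 fell (log2 -1.36, SE 0.26, adjusted p = 0.00447) while Cd177 rose (log2 1.28, SE 0.33, adjusted p = 0.0183), the latter not without WT_untreated 5 (adjusted p = 0.0521). With median scaling the surface colonocyte list did not pass (adjusted p = 0.121), nor with median scaling over probes detected on all arrays (adjusted p = 0.167).

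Of the remaining 19 lists none passed by camera, and their members past the threshold are counted here. Antimicrobial proteins counted 4 higher and 2 lower of 21 (median -0.12, adjusted p = 0.83), with a mean of 0.31 on the other side of 0 from the median. Interferon-stimulated genes counted 2 higher of 36 (median 0.31, adjusted p = 0.344) and MHC class I genes 1 higher of 16 (median 0.40, adjusted p = 0.0749). Chemokine and cytokine genes counted 1 higher and 2 lower of 16 (median 0.21, adjusted p = 0.982) and pattern recognition genes 1 higher and 1 lower of 25 (median -0.07, adjusted p = 0.772). Immediate early and heat shock genes counted 4 higher of 23 (median 0.13, adjusted p = 0.639), and Hspa1a of the heat shock response was 2.12 higher (SE 0.50, adjusted p = 0.0126). By limma 0 members passed among MHC class II genes (0 at an unadjusted p under 0.05, median 0.12, adjusted p = 0.83), lipogenesis genes (3 at an unadjusted p under 0.05, median 0.16, adjusted p = 0.568) and crypt base and stem cell markers (2 at an unadjusted p under 0.05, median -0.01, adjusted p = 0.98). Oxidative phosphorylation genes counted 3 lower of 36 (median 0.00, adjusted p = 0.344), enteroendocrine markers 1 higher and 1 lower of 14 (median -0.16, adjusted p = 0.317), tight junction and adhesion genes 1 higher and 2 lower of 27 (median -0.09, adjusted p = 0.114) and circadian genes 2 lower of 15 (median 0.22, adjusted p = 0.753). For chemokines, crypt markers, circadian genes and oxidative phosphorylation the camera direction was down while the median or the mean was not. Where the count adjusted over the list alone differed, it was 6 higher and 3 lower for antimicrobial proteins, 0 for interferon-stimulated genes, 2 and 3 for chemokines, 2 and 2 for pattern recognition, 2 and 6 for tight junctions and 2 lower for oxidative phosphorylation.

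Markers of other cell types did not pass as lists. Of 11 neutrophil, eosinophil and mast cell markers 3 rose (4 adjusted over the list alone, median 0.27, adjusted p = 0.114), among them the mast cell protease gene Mcpt4 (log2 1.22, SE 0.27, adjusted p = 0.0103). By limma 0 members passed among B cell markers (1 at an unadjusted p under 0.05, median -0.25, adjusted p = 0.354), T cell and intraepithelial lymphocyte markers (2 at an unadjusted p under 0.05, median -0.06, adjusted p = 0.558) and macrophage and dendritic cell markers (0 at an unadjusted p under 0.05, median -0.18, adjusted p = 0.344). Stromal, muscle and endothelial markers counted 1 higher and 1 lower of 13 (median -0.18, adjusted p = 0.624) and adipocyte and pancreas markers 1 lower of 7 (median -0.26, adjusted p = 0.49). The fibronectin gene Fn1 rose (log2 1.20, SE 0.26, adjusted p = 0.00783) and the lipoprotein lipase gene Lpl fell (log2 -1.35, SE 0.26, adjusted p = 0.00492). The mean leukocyte marker score was 0.10 ± 0.31 (SD, n = 5) in WT_untreated and 0.05 ± 0.53 (SD, n = 6) in KO_untreated.

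By limma, 2180 of 19993 probes differed between untreated KO and WT mice, 1110 higher and 1070 lower, of which 138 and 294 differed more than 2-fold. The replicate block gave 3358 and no filter 982. The count was 319 with median scaling, with the balance at 240 higher and 79 lower, and 42 of the 82 named gene values past the threshold did not pass there. It was 856 without KO_untreated 1, 1062 without KO_untreated 5, 1401 without WT_untreated 1, 1152 without WT_untreated 4 and 1069 without WT_untreated 5, and 36 of the 82 values were lost without at least one array. Descriptions of 5 of the 6 KO_untreated arrays carry a suffix that no other group has, and with KO_untreated 1, which lacks it, as the only KO array, the count was 225. The lone array is there assumed to vary like the other groups.

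With antibiotics the KO and WT epithelium differed in few genes, several of them neighbours of Pigr on chromosome 1. Besides Pigr, the sterol regulator gene Insig2 (2.41-fold, log2 -1.27, SE 0.17, adjusted p = 0.000525) and the histone demethylase gene Kdm5b (2.14-fold, log2 -1.10, SE 0.14, adjusted p = 0.000525) were lower in KO mice (n = 6 KO and 5 WT arrays). So were the transcription factor gene Sox13 (2.60-fold, log2 -1.38, SE 0.19, adjusted p = 0.000654) and Ctse, which encodes the protease cathepsin E (3.58-fold, log2 -1.84, SE 0.31, adjusted p = 0.0143). A probe of the glycolysis gene Pgk1, which is X-linked, was at least 2.98-fold higher (log2 1.87, SE 0.13, adjusted p = 1.19e-08). It was undetected on all 10 WT arrays and detected on all 12 KO arrays, while the second detected Pgk1 probe differed by 0.07. In untreated mice the differences were -1.47 for Insig2 (adjusted p = 1.95e-05), -1.28 for Kdm5b (adjusted p = 1.95e-05), -1.24 for Sox13 (adjusted p = 0.000662), -0.94 for Ctse (adjusted p = 0.0522) and 2.58 for the Pgk1 probe (at least 4.97-fold, adjusted p = 1.17e-11). Pgk1, Insig2, Kdm5b and Ctse fall outside the rule for named genes, since their called probe is not the brightest of the gene, and were chosen after their values were seen. Next by p with 1 probe per gene, without passing, came Ipo9, 79 genes from Pigr (-0.87, adjusted p = 0.0544, and -0.74 untreated, adjusted p = 0.00917), Cib3 at 1.02 (adjusted p = 0.0772), Eml2 at -1.38 (adjusted p = 0.284) and Sis at -1.20 (adjusted p = 0.342). They were followed by Cpne8 at -0.60 (adjusted p = 0.609), Muc1 at -0.94 (adjusted p = 0.863), Pla2g2a at 1.90 and C2cd4c at 0.62. Ipo9 passed without KO_antibiotic 2 or WT_antibiotic 1 (lowest adjusted p 0.0341), Cib3 without KO_antibiotic 6 (adjusted p = 0.0126) and Eml2 without WT_antibiotic 1 (adjusted p = 0.0101).

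In gene order from Pigr, Insig2 stood at -32, Ctse at 14, Sox13 at 43 and Kdm5b at 66. With 1 probe per gene, 1 of 98 tested genes within 100 neighbours was called with antibiotics against 0 of 10410 elsewhere (two-sided Fisher exact p = 0.00933, 8.61e-05 without KO_antibiotic 2, 0.000257 without WT_antibiotic 1 and 0.0458 without KO_antibiotic 6). It rests on Sox13 alone, so this p is no more than the share of tested genes that lie near Pigr. Without antibiotics these were 17 of 98 and 1252 of 10410 (odds ratio 1.54, two-sided Fisher exact p = 0.118), which passed without KO_untreated 3 (exact p = 0.0491) or WT_untreated 5 (exact p = 0.0492). Counting a gene when any of its probes was called, chosen after seeing the data, gave 4 of 98 against 1 of 10410 with antibiotics (two-sided Fisher exact p = 3.53e-08). Other probes of the same genes did not pass, at -0.42 for Insig2, 0.27 and -0.25 for Kdm5b and -0.78 and -0.49 for Ctse.

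**Figure D3:**
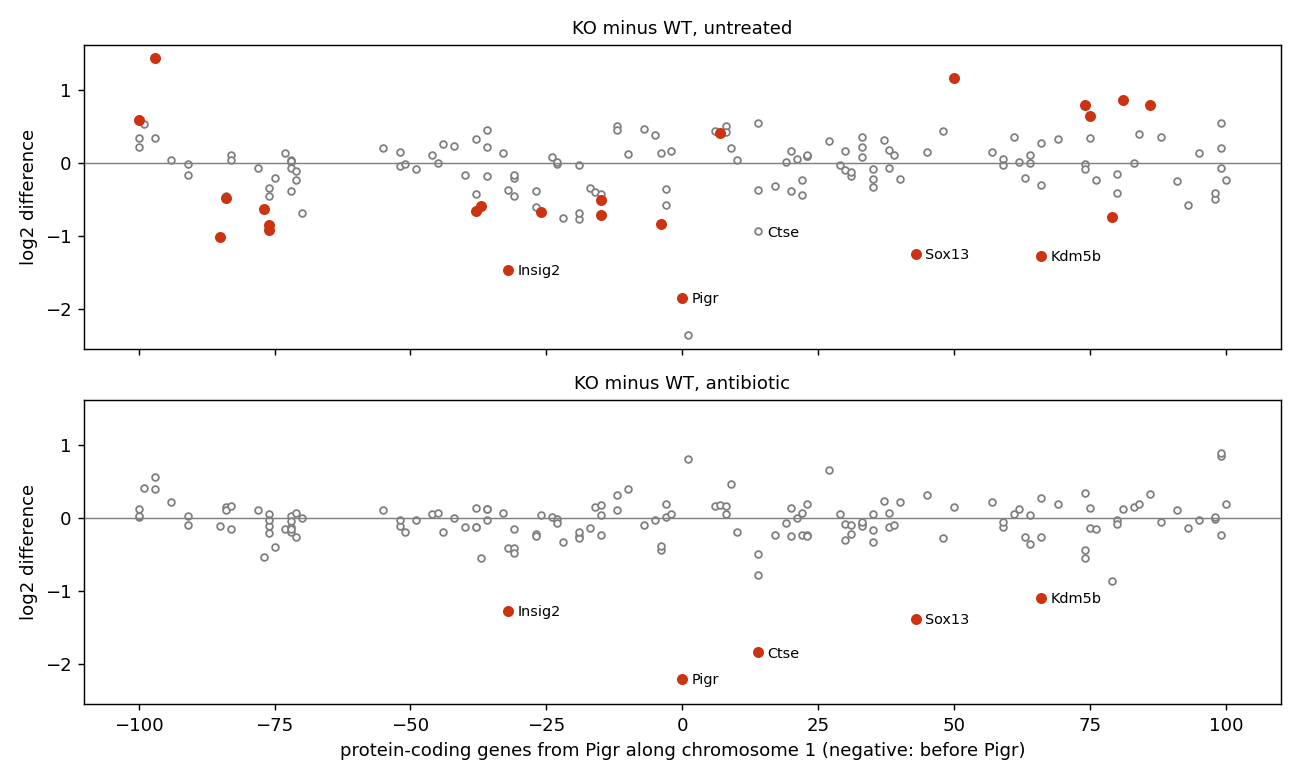
Log2 difference KO minus WT (y axis) of every tested probe by gene order from Pigr, 100 genes on each side (x axis, genes), in untreated mice and with antibiotics, where each point is a probe and red marks an adjusted p under 0.05. With antibiotics the red points are Insig2, Pigr, Ctse, Sox13 and Kdm5b.

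Several immune and secretory gene lists stood higher in antibiotic-treated KO mice than in treated WT mice, though no member passed in limma (at an unadjusted p under 0.05, 8 tuft cell and 5 MHC class II genes among them did), and none of these calls held with an estimated correlation. Tuft cell markers had a median of 0.50 over 13 genes (7 higher adjusted over the list alone, camera adjusted p = 9.81e-11, estimated-correlation adjusted p = 0.163). Avil was at 0.70 and Alox5 at 0.71. MHC class II genes had a median of 0.80 over 10 (adjusted p = 2.18e-07, estimated-correlation adjusted p = 0.39). H2-Ab1 was at 1.31 and Cd74 at 0.93. Interferon-stimulated genes had a median of 0.46 over 36 (adjusted p = 7.24e-08, estimated-correlation adjusted p = 0.648), and MHC class I genes 0.20 over 16 (adjusted p = 0.00545, estimated-correlation adjusted p = 0.66). Goblet cell markers were at 0.24 over 19 (adjusted p = 0.00102, estimated-correlation adjusted p = 0.439) and cell cycle genes at 0.19 over 32 (adjusted p = 0.00288, estimated-correlation adjusted p = 0.66). Markers of lymphocytes stood higher beside them, B cell and plasma cell markers at 0.49 over 10 (adjusted p = 0.00102, estimated-correlation adjusted p = 0.439) and T cell and intraepithelial lymphocyte markers at 0.39 over 18 (adjusted p = 5.75e-05, estimated-correlation adjusted p = 0.498). The leukocyte marker score was 0.07 ± 0.39 (SD, n = 6) in KO_antibiotic and -0.24 ± 0.31 (SD, n = 5) in WT_antibiotic.

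The other 20 lists did not pass in antibiotic-treated mice. Their medians and adjusted p were -0.14 and 0.773 for antimicrobial proteins (2 higher adjusted over the list alone), -0.03 and 0.643 for oxidases, 0.09 and 0.146 for chemokines and -0.03 and 0.883 for pattern recognition. They were -0.08 and 0.406 for xenobiotic metabolism, -0.02 and 0.146 for fatty acid oxidation, -0.10 and 0.151 for cholesterol synthesis, 0.00 and 0.887 for lipogenesis and 0.04 and 0.637 for oxidative phosphorylation. They were -0.14 and 0.0595 for enteroendocrine, 0.01 and 0.887 for crypt and -0.06 and 0.165 for surface colonocyte markers, 0.03 and 0.868 for tight junctions, 0.12 and 0.151 for the unfolded protein response, 0.05 and 0.711 for immediate early genes and -0.04 and 0.643 for circadian genes. For macrophage markers they were -0.01 and 0.643, for neutrophil, eosinophil and mast cell markers 0.01 and 0.31, for stromal markers -0.01 and 0.887 and for adipocyte and pancreas markers -0.24 and 0.0898. Median, mean and camera direction differed in sign for antimicrobial proteins (mean 0.22), pattern recognition, lipogenesis, crypt markers, tight junctions, and neutrophil, eosinophil and mast cell markers (mean -0.23). Ang4, an angiogenin with antimicrobial activity, was at 3.31 and the lectin gene Itln1 at 3.09 without passing, each higher on 5 of 6 KO arrays.

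By limma 6 of 19993 probes differed, 1 higher and 5 lower, and 654 had an unadjusted p under 0.05. Median scaling left 2 probes, 1 higher and 1 lower, and without KO_antibiotic 6 there were 12.

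The second question is what antibiotics changed in WT mice. With antibiotics, xenobiotic metabolism genes stood higher in WT mice and antimicrobial, MHC class II and cell cycle genes lower (n = 5 and 5 arrays). With an estimated correlation none of these calls held (adjusted p = 0.281, 0.105, 0.222 and 0.105 in this order). The fatty acid hydroxylase gene Cyp4b1 was 10.0-fold higher (log2 3.33, SE 0.45, adjusted p = 0.000155) and Sis, the gene of the brush border enzyme sucrase-isomaltase, 6.07-fold (log2 2.60, SE 0.29, adjusted p = 1.74e-05). Slc7a9, which encodes a cystine and amino acid transporter, was 4.11-fold higher (log2 2.04, SE 0.20, adjusted p = 3.68e-06). Pla2g2a, a secreted phospholipase that kills Gram-positive bacteria, was 17.8-fold lower (log2 -4.16, SE 0.52, adjusted p = 7.88e-05) and the antibacterial lectin gene Reg3g 8.52-fold (log2 -3.09, SE 0.52, adjusted p = 0.00125).

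Further rises were Cyp4b1-ps2 (10.7-fold, adjusted p = 0.000384), the peptidase gene Naaladl1 (7.81-fold, adjusted p = 4.11e-05), the clock output gene Dbp (6.73-fold, adjusted p = 0.0283), Casp14 (5.25-fold, adjusted p = 0.00737) and the cytochrome gene Cyp2d26 (4.99-fold, adjusted p = 0.000621). Others were the procollagen protease gene Bmp1 (4.31-fold, adjusted p = 0.000181) and Tef, a transcription factor gene related to Dbp (3.49-fold, adjusted p = 0.00399). Further falls were Ang4 (20.1-fold, adjusted p = 0.0408), Pla2g4c (at least 10.5-fold, adjusted p = 0.0142), Pnliprp2 (9.86-fold, adjusted p = 0.0447) and the goblet cell gene Retnlb (8.05-fold, adjusted p = 0.0119). Others were Dlk1 (6.85-fold, adjusted p = 9.81e-07), the interferon-induced gene Ifit2 (5.67-fold, adjusted p = 0.0277), Cd177 (5.38-fold, adjusted p = 0.000197) and the MHC class II loading gene H2-DMb1 (5.20-fold, adjusted p = 0.0218). Each changed the same way on 5 of 5 treated arrays against the untreated mean. Beyond all untreated arrays lay 2 of 5 treated arrays for Pla2g4c and Pnliprp2, 3 for Ang4 and Casp14 and 4 for Ifit2. For the other genes in this paragraph it was 5 of 5. Calls were lost for Ang4 and Pnliprp2 without WT_antibiotic 1, 2, 3 or 4 or WT_untreated 1, 3 or 4 (highest adjusted p 0.137 and 0.153), and for Dbp without WT_antibiotic 1 or 2 or WT_untreated 1, 3 or 4 (0.0845). The same held for Ifit2 without WT_antibiotic 2, 4 or 5 or WT_untreated 3, 4 or 5 (0.0939). They were also lost for Pla2g4c without WT_untreated 4 (adjusted p = 0.0538), Retnlb without WT_untreated 3 (adjusted p = 0.0501) and H2-DMb1 without WT_antibiotic 4 or WT_untreated 3 or 4 (highest adjusted p 0.0758).

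Cell cycle genes fell in 16 of 32 cases (23 adjusted over the list alone, median -0.82, camera adjusted p = 1.1e-17, estimated-correlation adjusted p = 0.105). The spindle checkpoint gene Bub1b was at -1.27 (SE 0.19, adjusted p = 0.00049) and its target gene Cdc20 at -1.37 (SE 0.23, adjusted p = 0.00107). The unfolded protein response had 6 of 23 lower (10 adjusted over the list alone, median -0.48, adjusted p = 3.95e-07, estimated-correlation adjusted p = 0.105). They included Chac1 at -2.04 (SE 0.37, adjusted p = 0.00217). Of 10 MHC class II genes 5 fell (9 adjusted over the list alone, median -1.52, adjusted p = 2.26e-07, estimated-correlation adjusted p = 0.222). They included H2-Ab1 at -2.06 (SE 0.49, adjusted p = 0.0166), whose call was lost without WT_antibiotic 5 or WT_untreated 3 or 4 (highest adjusted p 0.066). Interferon-stimulated genes fell in 3 of 36 cases (7 adjusted over the list alone, median -0.60, adjusted p = 4.65e-07, estimated-correlation adjusted p = 0.41). Goblet cell markers fell in 5 of 19 (9 adjusted over the list alone, median -0.44, adjusted p = 4.08e-05, estimated-correlation adjusted p = 0.222). Spink4 was at -1.50 (SE 0.29, adjusted p = 0.00383). Antimicrobial proteins fell in 5 of 21 (6 adjusted over the list alone, median -0.38, adjusted p = 0.00198, estimated-correlation adjusted p = 0.105). Oxidase and acute phase genes went both ways, 2 higher and 3 lower of 14 (2 and 5 adjusted over the list alone, median -0.47, adjusted p = 0.0418, estimated-correlation adjusted p = 0.281). The oxidase gene Nox1 was at -1.70 (SE 0.37, adjusted p = 0.00894) and the acute phase gene Saa1 at 1.62 (SE 0.23, adjusted p = 0.000197). Crypt base and stem cell markers had 0 of 15 past (3 lower adjusted over the list alone and 5 lower at an unadjusted p under 0.05, median -0.20, adjusted p = 0.0253, estimated-correlation adjusted p = 0.281).

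Xenobiotic metabolism genes counted 6 higher and 1 lower of 32 (13 and 2 adjusted over the list alone, median 0.37, adjusted p = 0.000992, estimated-correlation adjusted p = 0.281), Cyp4f14 at 1.35 (SE 0.20, adjusted p = 0.000353) and Cyp2c55 at -1.31 (SE 0.25, adjusted p = 0.00378). Circadian genes rose in 3 of 15 (4 higher and 1 lower adjusted over the list alone, median 0.30, adjusted p = 0.0472, estimated-correlation adjusted p = 0.281). Dbp varied between treated arrays from 7.16 on WT_antibiotic 5 to 10.01 on WT_antibiotic 2, and from 6.37 on KO_antibiotic 6 to 10.29 on KO_antibiotic 2. Cholesterol synthesis genes had 0 of 18 past (4 higher at an unadjusted p under 0.05, median 0.20, adjusted p = 0.0418, estimated-correlation adjusted p = 0.347), a call lost with median scaling (adjusted p = 0.0575). T cell and intraepithelial lymphocyte markers stood lower beside the epithelial lists, with 0 of 18 past (2 lower adjusted over the list alone and 4 at an unadjusted p under 0.05, median -0.40, adjusted p = 0.00455, estimated-correlation adjusted p = 0.456).

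The remaining 16 lists did not pass in WT mice. Members past the threshold, median and adjusted p were 1 lower, -0.14 and 0.0513 for MHC class I, 2 lower, -0.20 and 0.0924 for chemokines, and 1 higher and 2 lower, -0.14 and 0.125 for pattern recognition. They were 2 higher, 0.10 and 0.158 for fatty acid oxidation, 1 higher and 2 lower, 0.16 and 0.991 for lipogenesis (mean -0.07), and 1 higher, 0.08 and 0.158 for oxidative phosphorylation. They were 2 higher and 1 lower, 0.21 and 0.0591 for surface colonocyte markers, where the sodium channel gene Scnn1g rose by 1.75 (SE 0.25, adjusted p = 0.000197). They were 1 higher and 1 lower, -0.03 and 0.938 for tight junctions, with the camera direction up, and 1 higher, -0.25 and 0.0729 for immediate early genes. Enteroendocrine markers (0.24 and 0.244), tuft cell markers (-0.22 and 0.0513), B cell markers (-0.55 and 0.119), macrophage markers (0.14 and 0.715), neutrophil, eosinophil and mast cell markers (-0.05 and 0.715) and stromal markers (0.02 and 0.805) had 0 members past in limma, with 0, 2, 5, 0, 0 and 2 at an unadjusted p under 0.05. Adipocyte and pancreas markers had 1 higher (0.16 and 0.715), the elastase gene Cela1 at 1.53 (SE 0.29, adjusted p = 0.00329). Adjusted over the list alone the count differed for chemokines (2 higher and 4 lower), lipogenesis (3 and 3), surface colonocyte markers (8 and 2), immediate early genes (2 higher) and adipocyte and pancreas markers (1 and 1).

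By limma 950 probes differed, 497 higher and 453 lower, with 2276 under array weights and 550 with no filter. Median scaling gave 237, with 76 higher and 161 lower, and 27 of the 63 named gene values past the threshold did not pass there. The count was 541, 608, 505 and 515 without WT_antibiotic 1, 2, 4 and 5 and 629, 411 and 480 without WT_untreated 1, 3 and 4, and 28 of the 63 values were lost without at least one array.

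In KO mice antimicrobial, oxidase, goblet cell and cell cycle genes stood lower with antibiotics and xenobiotic metabolism genes higher (n = 6 and 6 arrays). The suffix on 5 of the 6 KO_untreated descriptions largely runs with treatment in this comparison. Cyp4b1 was 11.8-fold higher (log2 3.56, SE 0.41, adjusted p = 4.26e-06) and Plscr4, a phospholipid scramblase gene, 4.73-fold (log2 2.24, SE 0.21, adjusted p = 3.56e-07). Mcpt1 was 14.5-fold lower (log2 -3.86, SE 0.58, adjusted p = 7.08e-05), Cma2 11.1-fold (log2 -3.47, SE 0.42, adjusted p = 6.64e-06), Reg4 11.9-fold (log2 -3.57, SE 0.47, adjusted p = 1.51e-05) and Duoxa2 11.8-fold (log2 -3.56, SE 0.29, adjusted p = 5.96e-08). Pla2g4c, a cytosolic phospholipase gene, was at least 59.1-fold lower (log2 -6.26, SE 0.79, adjusted p = 1.11e-05) and Pla2g2a 27.3-fold (log2 -4.77, SE 0.48, adjusted p = 9.82e-07).

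Further rises were Cyp4b1-ps2 (12.1-fold, adjusted p = 1.44e-05), Naaladl1 (7.98-fold, adjusted p = 1.85e-06), the sodium pump regulator gene Fxyd4 (6.33-fold, adjusted p = 0.000443) and Bmp3 (6.06-fold, adjusted p = 4.01e-05). Others were the metallothionein gene Mt2 (5.03-fold, adjusted p = 0.000323), Casp14 (4.67-fold, adjusted p = 0.00176), Nbl1 (4.44-fold, adjusted p = 1.45e-05) and Bmp1 (4.43-fold, adjusted p = 9.48e-06). Further falls were Pnliprp2 (30.3-fold, adjusted p = 0.000399), Ang4 (14.1-fold, adjusted p = 0.0246), the gasdermin gene Gsdmc4 (11.4-fold, adjusted p = 4.23e-06) and Hspa1a (10.1-fold, adjusted p = 4.01e-05). Each changed the same way on 6 of 6 treated arrays against the untreated mean, and the call of Ang4 was lost without KO_antibiotic 6 (adjusted p = 0.0573).

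**Figure D4:**
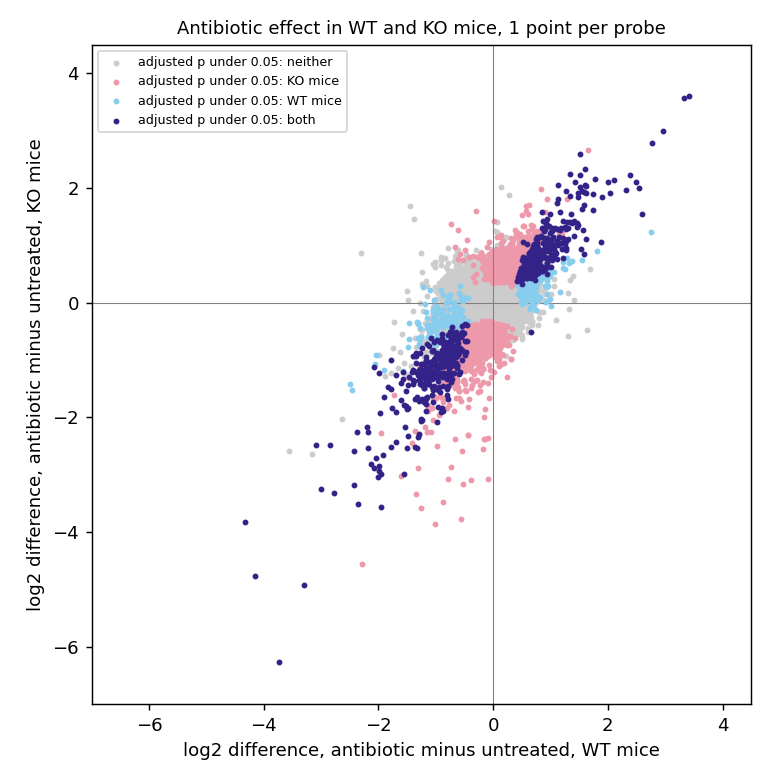
Log2 difference antibiotic minus untreated in WT mice (x axis) and in KO mice (y axis), where each point is a tested probe. The correlation across probes was 0.585 (Pearson).

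Of the lists, 7 passed also with an estimated correlation in KO mice. Cell cycle genes fell in 24 of 32 cases (27 adjusted over the list alone, median -0.96, camera adjusted p = 8.13e-20, estimated-correlation adjusted p = 0.0431). Cdc20 was at -1.68 (SE 0.21, adjusted p = 9.03e-06). The unfolded protein response fell in 13 of 23 (15 adjusted over the list alone, median -0.53, adjusted p = 1.92e-13, estimated-correlation adjusted p = 0.0136). Creld2 was at -1.83 (SE 0.20, adjusted p = 2.19e-06) and Asns at -1.45 (SE 0.16, adjusted p = 2.19e-06). Oxidase and acute phase genes counted 1 higher and 10 lower of 14 (2 and 10 adjusted over the list alone, median -1.07, adjusted p = 8.66e-07, estimated-correlation adjusted p = 0.0136). Duox2 was at -1.82 (SE 0.24, adjusted p = 1.45e-05) and Nox1 at -2.42 (SE 0.33, adjusted p = 2.93e-05). Goblet cell markers counted 1 higher and 10 lower of 19 (1 and 11 adjusted over the list alone, median -0.58, adjusted p = 1.34e-07, estimated-correlation adjusted p = 0.0478). Spink4 was at -2.53 (SE 0.26, adjusted p = 1.73e-06). Antimicrobial proteins fell in 8 of 21 (1 higher and 10 lower adjusted over the list alone, median -0.36, adjusted p = 0.00152, estimated-correlation adjusted p = 0.0478). Retnlb was at -3.25 (SE 0.62, adjusted p = 0.000898) and Reg3b at -2.54 (SE 0.48, adjusted p = 0.000844). Xenobiotic metabolism genes rose in 14 of 32 (22 adjusted over the list alone, median 0.71, adjusted p = 6.69e-11, estimated-correlation adjusted p = 0.0478). Cyp3a13 was at 1.58 (SE 0.20, adjusted p = 1.11e-05). Surface colonocyte markers counted 11 higher and 1 lower of 30 (12 and 2 adjusted over the list alone, median 0.42, adjusted p = 0.000239, estimated-correlation adjusted p = 0.0431). The metalloprotease gene Mep1a was at 1.29 (SE 0.22, adjusted p = 0.000234) and Cd177 at -3.17 (SE 0.31, adjusted p = 8.57e-07).

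Another 10 lists passed with the preset correlation alone. Fatty acid oxidation genes rose in 5 of 31 (10 adjusted over the list alone, median 0.32, adjusted p = 0.000522, estimated-correlation adjusted p = 0.216). Oxidative phosphorylation genes rose in 4 of 36 (4 adjusted over the list alone, median 0.14, adjusted p = 0.00435, estimated-correlation adjusted p = 0.248). Circadian genes rose in 2 of 15 (2 adjusted over the list alone, median 0.44, adjusted p = 0.0242, estimated-correlation adjusted p = 0.19). The clock repressor gene Cry2 was at 0.92 (SE 0.17, adjusted p = 0.000757). Cholesterol synthesis genes fell in 4 of 18 (6 adjusted over the list alone, median -0.41, adjusted p = 0.00152, estimated-correlation adjusted p = 0.171). Fdps was at -0.89 (SE 0.16, adjusted p = 0.000485). Tuft cell markers fell in 4 of 13 (7 adjusted over the list alone, median -0.53, adjusted p = 0.00111, estimated-correlation adjusted p = 0.248). Avil was at -0.90 (SE 0.21, adjusted p = 0.00479). Crypt markers fell in 4 of 15 (4 adjusted over the list alone, median -0.26, adjusted p = 0.0242, estimated-correlation adjusted p = 0.265). Interferon-stimulated genes fell in 3 of 36 (1 adjusted over the list alone, median -0.50, adjusted p = 0.00152, estimated-correlation adjusted p = 0.546). MHC class I genes fell in 3 of 16 (8 adjusted over the list alone, median -0.43, adjusted p = 0.0145, estimated-correlation adjusted p = 0.523). MHC class II genes fell in 1 of 10 (3 adjusted over the list alone, median -0.97, adjusted p = 0.00787, estimated-correlation adjusted p = 0.449). Neutrophil, eosinophil and mast cell markers fell beside the epithelial lists in 4 of 11 (5 adjusted over the list alone, median -0.11, adjusted p = 0.00787, estimated-correlation adjusted p = 0.13). The mast cell carboxypeptidase gene Cpa3 was at -1.46 (SE 0.32, adjusted p = 0.00327).

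The remaining 11 lists did not pass in KO mice. Members past the threshold, median and adjusted p were 3 higher and 6 lower, -0.12 and 0.537 for chemokines, 3 lower, 0.00 and 0.427 for pattern recognition and 3 lower, -0.09 and 0.431 for lipogenesis. They were 1 lower, 0.21 and 0.188 for enteroendocrine markers, 3 higher and 1 lower, 0.13 and 0.0875 for tight junctions and 5 lower, -0.08 and 0.0879 for immediate early genes. Hspa1b was at -2.38 (SE 0.44, adjusted p = 0.000685). Of other cell types they were 1 lower, 0.09 and 0.816 for T cell markers, 2 higher, 0.13 and 0.248 for macrophage markers, 1 lower, 0.17 and 0.339 for stromal markers and 1 higher, 0.11 and 0.607 for adipocyte and pancreas markers. B cell markers had 0 of 10 past in limma and 0 at an unadjusted p under 0.05 (median 0.34, adjusted p = 0.188). The count adjusted over the list alone differed for lipogenesis (4 lower), immediate early genes (6 lower) and stromal markers (1 higher and 1 lower).

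By limma 2478 probes differed, 1066 higher and 1412 lower, the count without KO_antibiotic 3 and 4 being 1886. Median scaling gave 1283, with 377 higher and 906 lower, and 17 of the 99 named gene values past the threshold did not pass there. With KO_untreated 1 as the only untreated KO array the count was 420, and 21 of the 99 values were lost without at least one array.

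**Figure D5:**
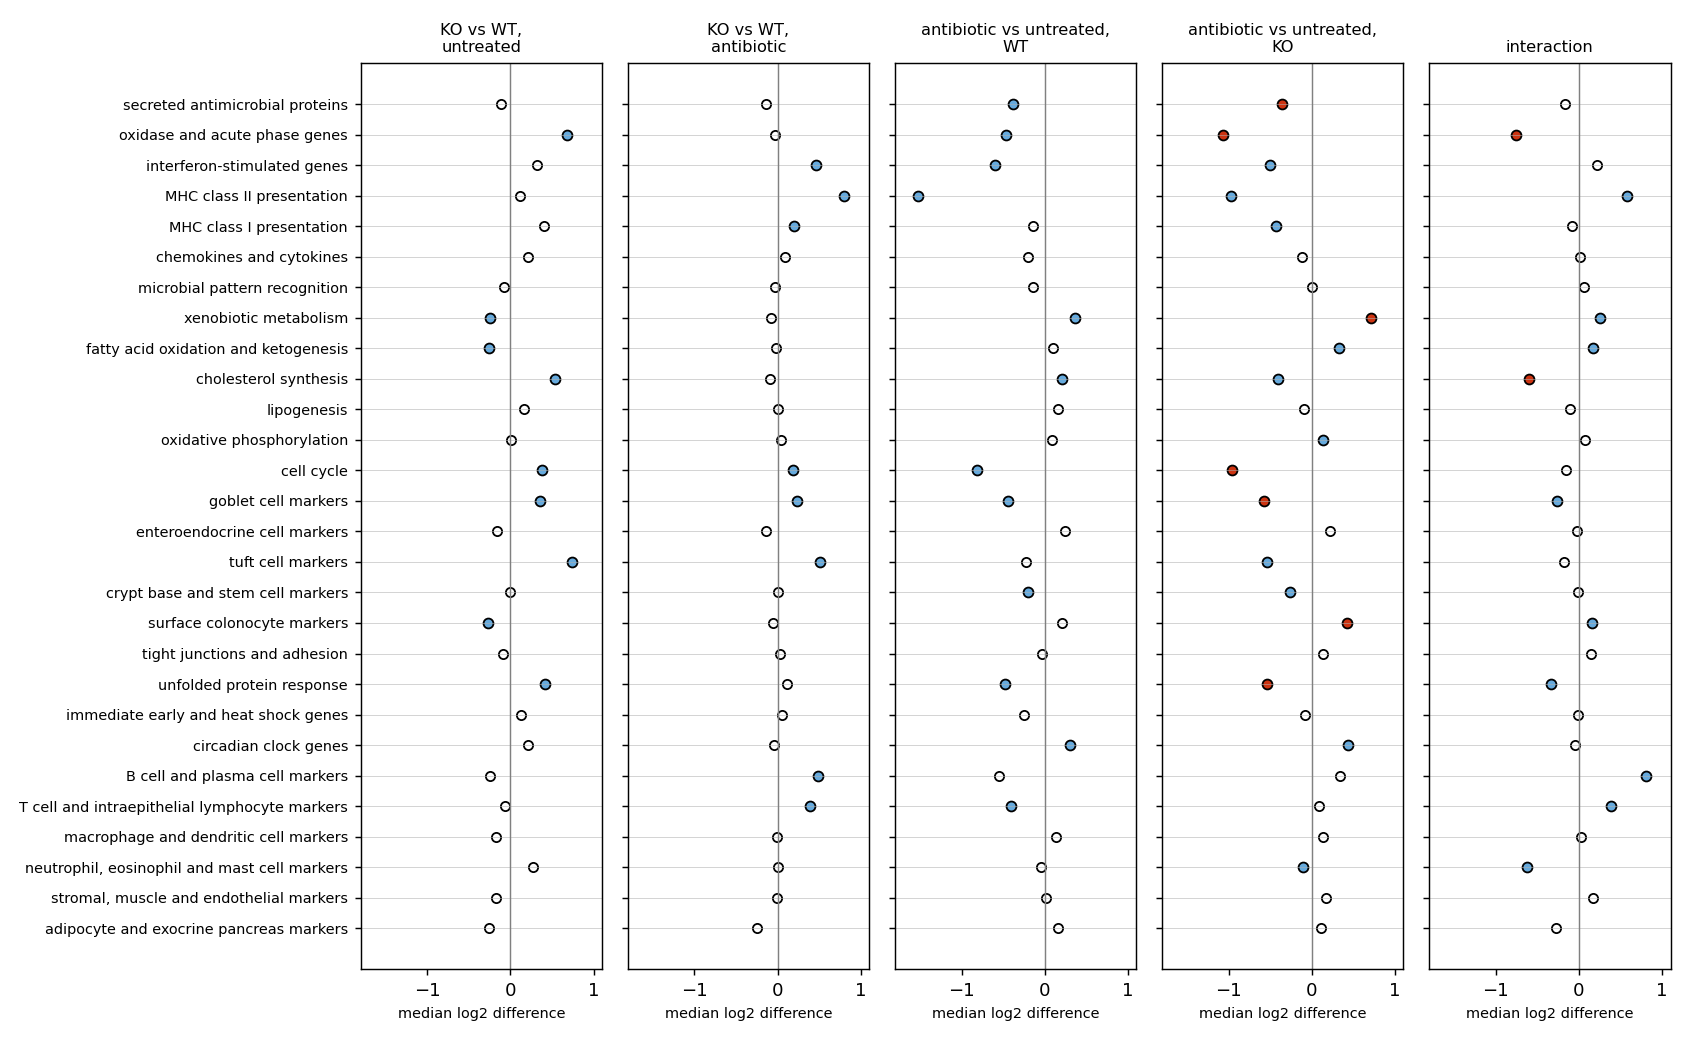
Median log2 difference (x axis) of the 28 gene lists (y axis) in the 5 contrasts, where each point is a list. White points did not pass by camera, blue points passed with the preset correlation and red points also with an estimated one, 7 of them for antibiotics in KO mice and 2 for the interaction.

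The last comparison asks whether antibiotics acted differently in the genotypes. A probe of Defa3 (ILMN_2524832) differed between genotypes in its antibiotic effect (log2 -2.71, SE 0.43, adjusted p = 0.0148), with mean levels of 4.63 in WT_untreated, 4.24 in WT_antibiotic, 7.40 in KO_untreated and 4.30 in KO_antibiotic. An unnamed probe, ILMN_1254739, did so too (log2 -3.21, SE 0.48, adjusted p = 0.0129), with means of 4.80, 4.24, 8.06 and 4.29 in the same order. In all groups but KO_untreated these means lay within or below the lowest detected levels of the arrays, 4.66 to 4.89, so a fall in WT mice had little room to show. Next by p, without passing, came Defa20 at -2.25 (adjusted p = 0.0689), another Defa3 probe at -2.63 (adjusted p = 0.0689) and P4ha2 at -0.89 (adjusted p = 0.107). They were followed by Sult1d1 at 1.91 (adjusted p = 0.126), Sult1a1 at 1.07 (adjusted p = 0.126), Scgb2b27 at -1.32 (adjusted p = 0.129), Zfp37 at 1.55 (adjusted p = 0.129), Slc29a4 at -2.13 (adjusted p = 0.131), Defa23 at -1.71 (adjusted p = 0.161) and Fdps at -1.04 (adjusted p = 0.161). Of these, Defa20 and this Defa3 probe passed without WT_untreated 3 or KO_untreated 3 or 5 (lowest adjusted p 0.000841 and 0.00495), Slc29a4 without WT_untreated 3 or KO_untreated 3 (lowest 0.0158) and Defa23 without KO_untreated 3 or 5 (lowest 0.0130). Sult1a1 (0.0187) and Scgb2b27 (0.0300) passed without WT_untreated 3.

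Cholesterol synthesis genes had a median of 0.20 with antibiotics in WT mice and -0.41 in KO mice, and the difference was past the threshold (median -0.60 over 18, 8 adjusted over the list alone, camera adjusted p = 2.19e-08, estimated-correlation adjusted p = 0.0267). Oxidase and acute phase genes, at -0.47 in WT and -1.07 in KO mice, differed too (median -0.75 over 14, 2 adjusted over the list alone, adjusted p = 1.3e-05, estimated-correlation adjusted p = 0.0267). With the preset correlation alone, goblet cell markers (median -0.26, adjusted p = 0.0352, estimated-correlation adjusted p = 0.545), the unfolded protein response (median -0.33, adjusted p = 0.00011, estimated-correlation adjusted p = 0.233) and neutrophil, eosinophil and mast cell markers (median -0.62, adjusted p = 0.00866, estimated-correlation adjusted p = 0.233) had differences below 0 as well. Xenobiotic metabolism (median 0.25, adjusted p = 8.21e-05, estimated-correlation adjusted p = 0.343), fatty acid oxidation (median 0.17, adjusted p = 0.0213, estimated-correlation adjusted p = 0.545) and surface colonocyte genes (median 0.16, adjusted p = 0.0303, estimated-correlation adjusted p = 0.343) had differences above 0. With median scaling fatty acid oxidation (adjusted p = 0.0589) and surface colonocyte markers (adjusted p = 0.113) did not pass. MHC class II genes (median 0.57, adjusted p = 0.0136, estimated-correlation adjusted p = 0.57) and markers of B cells (median 0.80, adjusted p = 0.00355, estimated-correlation adjusted p = 0.437) and T cells (median 0.39, adjusted p = 0.00313, estimated-correlation adjusted p = 0.545) stood higher. By limma no member of these lists passed, while adjusted over the list alone 5 of the unfolded protein response and 2 mast cell and related markers were lower and 2 xenobiotic metabolism genes higher, and 9 cholesterol synthesis and 5 oxidase genes were lower at an unadjusted p under 0.05. The other 17 lists did not pass, and median, mean and camera direction differed in sign for circadian genes, adipocyte and pancreas markers and enteroendocrine markers.

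By limma 2 probes passed, both lower, and 1755 had an unadjusted p under 0.05. The count was 0 with median scaling, the authors' values, no background correction or no filter, and without KO_antibiotic 3 and 4. It was 17 with array weights and 13 with KO_untreated 1 as the only untreated KO array. Without single arrays it was 22 (WT_untreated 3), 13, 9 and 4 (KO_untreated 3, 5 and 6) and 1 each (WT_untreated 1, 2 and 5).

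The antibiotic effects of the genotypes went together. Across the 19993 probes, which are not independent replicates, their correlation was 0.585 (Pearson) and 0.407 (Spearman). The jackknife SD of the Pearson value, from each array left out in turn, was 0.170. In both genotypes 300 probes rose and 321 fell, where 26.5 and 32.0 shared probes would follow from independent calls, and 1 probe went opposite ways. The KO effects with and without antibiotics correlated at 0.465 (Pearson) and 0.440 (Spearman), with a Pearson value of 0.301 without KO_antibiotic 2. Its jackknife SD was 0.319, so this correlation is loosely known. Of the 2180 probes called in untreated mice 83.2% had the same sign with antibiotics. Their median size was 0.741 untreated, and with antibiotics the median in the same direction was 0.159. The KO effect in untreated mice and the antibiotic effect in KO mice correlated at -0.591 and share the KO_untreated arrays. Simulated noise without any effect gave -0.476 through the shared arrays, but a covariance of -0.0194 against -0.104 observed. With the KO_untreated arrays divided between both effects, so that none was shared, 20 splits gave a mean correlation of -0.452 (-0.640 to -0.252). Their mean covariance was -0.0860. Of the probes higher in untreated KO mice 623 fell with antibiotics and of those lower 205 rose, where 78.4 and 57.1 would follow from independent calls. In the same direction there were 0 probes called in both. The shared arrays also contribute to these counts.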

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

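The contrasts, the 28 gene lists, the leukocyte covariate and the test of noise in the antibiotic arrays in this part were fixed before their results were seen. The rule of the noise test was changed after, and the rule for reading the leukocyte covariate was written after. The other tests of explanations and the 4 added lists were chosen after.

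Pigr, the Pgk1 probe, Xist, Eif2s3y, Kdm5d, the number of detected probes, the mean signal and the leukocyte score were each examined in the 4 groups. In 4 of these 32 sets one array lay far from the others, where chance gives about 1 in 20. Pigr stood at 12.50 on WT_untreated 3 and at 12.01 on WT_antibiotic 4, above the rest of their groups. Xist, the RNA of the inactive X chromosome, stood at 5.05 on KO_untreated 1 and at 10.40 on KO_antibiotic 4. The value of 5.05 lay near the lowest detected level of that array, 4.84. It was below the same probe on WT_untreated 5 (5.10) and WT_antibiotic 5 (5.57).

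The antibiotic effect differed between genotypes for the unnamed probe ILMN_1254739 (-3.21) and for Defa3 (-2.71). The mean levels of both probes lay at background in all groups but KO_untreated, so a fall in WT mice had little room to show and these values do not establish that antibiotics acted differently. Dealing the residuals of an additive fit to the arrays gave as many as 2 probes in 3 of 100 deals, the real one included, and the highest other gave 13. So few deals speak against chance for the count, but this test replaced another after its result was seen, and the count was 0 with median scaling over all probes, the authors' values, no background correction or no filter. By list the differences had medians of -0.75 for oxidase and acute phase genes, 0.57 for MHC class II, 0.25 for xenobiotic metabolism, 0.17 for fatty acid oxidation and -0.60 for cholesterol synthesis. For goblet cell markers the median was -0.26, for surface colonocyte markers 0.16, for the unfolded protein response -0.33, for B cell markers 0.80, for T cell markers 0.39 and for neutrophil, eosinophil and mast cell markers -0.62. Of these 11 calls 2, for cholesterol synthesis and for oxidase and acute phase genes, held with an estimated correlation, and the others had adjusted p from 0.233 to 0.57. For antibiotics in WT mice 1 of 100 splits, the real one, gave as many as 950 probes (highest other 519). In KO mice 1 of 100, the real one, gave as many as 2478 (highest other 1872). This argues against chance for both counts, though 100 splits cannot exclude it. The split with 1872 set KO_untreated 1, 3 and 5 and KO_antibiotic 1 to 3 against the rest, a structure that treatment does not describe.

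With antibiotics, 6 probes differed between KO and WT mice, 5 of them for Pigr and genes in its neighbourhood. Of 100 splits of these arrays 5 gave as many, the real one included, so chance was not excluded for the count, and the highest gave 3728 by setting WT_antibiotic 1 and 2 and KO_antibiotic 1 to 3 against the rest, a structure among the arrays that the groups do not describe, but in the untreated arrays fitted alone all 6 probes differed in the same direction (highest adjusted p over the 6 = 0.0173, for Ctse), which argues against chance for the single probes. Sequence of the donor strain that stayed linked to the disrupted gene may account for the neighbours, which were enriched near Pigr (two-sided Fisher exact p = 3.53e-08) in a test made on the genes that raised the question. RNA of a Pgk1-derived cassette might account for the Pgk1 probe, since the second detected Pgk1 probe differed by 0.0701, but the targeting construct is not given in the sources used here, and a sequence variant under the probe cannot be told apart from it. A response of these genes to the loss of the receptor stays open as untested.

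Many probes (2180) differed between genotypes without antibiotics and few (6) with them. Of 100 splits of the untreated arrays 1, the real one, gave as many as 2180 (highest other 1001). This argues against chance for the larger count, though 100 splits cannot exclude it. Leukocyte content on balance as the whole cause was argued against, since 2129 probes differed with the leukocyte score as a covariate. The mean score was 0.10 in WT_untreated and 0.05 in KO_untreated. It averages the markers of all leukocytes, so a change in a single cell type, such as mast cells, was not tested by it. More noise in the antibiotic arrays as the whole cause was tested by the variance of the KO effect beyond sampling error. It was 26.6 times as large untreated (0.131 against 0.00492). Without one array it ranged from 0.105 to 0.146 untreated and from -0.00718 to 0.0240 with antibiotics. The rule fixed before asked for a ratio over 2 in every fit without one array. It was not met, since the ratio had no value in 4 of 22 fits, where the antibiotic variance was below 0. Untreated was over 2 times as large in all 22, a reading made after they were seen that holds by itself in those 4. Under the fixed rule the explanation stays open, while the separate ranges argue against noise as the whole cause. A state of the gut that follows cage or cohort cannot be told apart from genotype, since cages are not in the labels. A suffix on 5 of the 6 KO_untreated descriptions, found in no other group, largely runs with genotype here. Its meaning is not given in the sources used here, so a batch cannot be told apart from genotype. The same holds for every comparison that uses the KO_untreated arrays. On a score along the antibiotic effect of KO mice, WT_untreated averaged 0.60 ± 0.25 (SD, n = 5) and WT_untreated 3 reached 0.95. KO_untreated averaged 0.94 ± 0.06 (SD, n = 6) on a different score, along the antibiotic effect of WT mice. The values of the genotypes therefore cannot be set against each other. An effect of the receptor's loss that needs the microbiota may also account for the pattern and was not tested.

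The Paneth cell genes Defa3 and Defa20 and the pancreatic genes Pnliprp2 (adjusted p = 0.0508 without WT_untreated 5) and Clps (highest adjusted p 0.0676 without one array) were higher in untreated KO mice, and of 9 tested Paneth cell markers 3 rose (median 1.64, camera adjusted p = 0.00173, estimated-correlation adjusted p = 0.0723). The Paneth cell list was written after these rises were seen and holds Defa3 and Defa20, so it is no separate support. Small-intestinal tissue in the preparations was argued against by the 8 ileal enterocyte markers that are dim in WT arrays, whose group medians differed by 0.18 (median, SD 0.32, highest 0.52) where Defa3 rose by 2.61 and Defa20 at least 3.88-fold between group means, with medians for Fabp6 of 5.11 in WT and 5.58 in KO arrays. Pancreatic tissue was argued against by 7 dim pancreatic genes, Pnliprp1 among them, with a median of 0.16 (SD 1.04, highest 2.75 for Pnliprp1) where Clps rose by 2.48 and Pnliprp2 by 3.35 between group medians, but WT_untreated 4 had Amy2a5 at 13.31, Cela2a at 11.19, Ctrl at 8.85, Cela3b at 8.49 and Clps at 11.32, as pancreatic tissue on that array would give, and Clps differed by 2.73 without it (adjusted p = 0.0121), while Amy2a5 was at most 5.38 on KO_untreated arrays. A type 2 response could raise these genes together with Mcpt1, Cma2 and tuft cell genes, and 7 of its 19 tested genes rose (median 0.71, camera adjusted p = 0.000552), but with an estimated correlation the adjusted p was 0.183, and 13 of its members are in the fixed lists, so it stays open. No cytokine measurement was used here.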

How the results depend on the processing

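Median scaling over detected probes, the number of detected probes as a covariate, the fit without KO_antibiotic 3 and 4, and KO_untreated represented by the array without a suffix were chosen after seeing the data. The cause of the changes below was not tested except where stated. Median scaling, where nothing else is said, is over all probes, most of them undetected on each array. No named gene value reversed, and of 246 past the threshold 87 fell short with median scaling, 19 with median scaling over detected probes, 17 with no background correction, 10 with the authors' values, 7 with array weights and 5 with the replicate block.

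With median scaling the counts were 319 (KO against WT untreated), 2 (the same with antibiotics), 237 (antibiotics in WT), 1283 (antibiotics in KO) and 0 (interaction), and Pigr with antibiotics stood at -2.04 without passing. With no filter they were 982 for KO against WT untreated, 550 for antibiotics in WT and 0 for the interaction, more probes being tested. With array weights they were 2276 for antibiotics in WT and 17 for the interaction, which was 0 with the authors' values and with no background correction. The replicate block gave 3358 for KO against WT untreated. The array without a suffix alone, which leaves 1 KO_untreated array, gave 225 for KO against WT untreated, 420 for antibiotics in KO and 13 for the interaction. Without KO_antibiotic 3 and 4 the interaction was 0. By limma these counts of 0 stand beside 1755 probes at an unadjusted p under 0.05 in the fit reported.

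With an estimated correlation 0 lists passed for KO against WT untreated, 0 with antibiotics, 0 for antibiotics in WT, 7 for antibiotics in KO and 2 for the interaction, against 9, 8, 12, 17 and 11 with the preset one. By fry these were 8, 0, 10, 16 and 2. With 200 neighbours on each side the genes near Pigr passed in untreated mice (exact p = 0.0189).

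Leaving out each array in turn gave 856 to 2081 probes for KO against WT untreated, 5 to 12 with antibiotics, 411 to 1314 for antibiotics in WT, 2052 to 2460 for antibiotics in KO and 1 to 22 for the interaction. The exact p for genes near Pigr ranged from 0.0491 to 0.585 untreated. Pigr ranged from -2.00 to -1.64 untreated and from -2.38 to -2.08 with antibiotics. A slide block was not run. The leukocyte covariate (2129, 8, 853, 2503 and 2 probes) and the stricter filter (2234, 7, 1058, 2373 and 2) stayed within 1.5 times the reported counts. Signal near background limits the rest, since probes detected on fewer than 5 arrays were not tested.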

Other observations

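Everything in this part was chosen after the results were seen.

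Of the gene lists written later, Paneth cell markers and type 2 response genes stood lower in KO mice given antibiotics. Of 9 tested Paneth cell markers 4 fell there (median -1.85, estimated-correlation adjusted p = 0.0064), against 1 of 9 in WT mice (median -0.14, estimated-correlation adjusted p = 0.248), where Defa3, Defa20 and Defa23 stood near background before treatment, at 4.95, 4.39 and 4.61, and had little room to fall. Of 19 type 2 response genes 11 fell (median -0.76, estimated-correlation adjusted p = 0.0202), against 4 of 19 in WT mice (median -0.38, estimated-correlation adjusted p = 0.217). With an estimated correlation the difference between genotypes had an adjusted p of 0.236 for this list and 0.022 for the Paneth cell markers, where the background in WT mice leaves its meaning open. The Paneth cell list holds Defa3 and Defa20, whose changes were seen before it was written, so its p-values are no separate support.

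Arrays within a group differed in the same genes. WT_untreated 3 and 4 stood at 13.96 and 13.67 for Ang4, 12.07 and 10.86 for Pla2g4c and 8.21 and 8.41 for Mcpt1. On a score along the antibiotic effect of KO mice, WT_untreated 1 to 5 stood at 0.54, 0.35, 0.95, 0.77 and 0.42.

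The labels call all mice male. Xist on KO_antibiotic 4 stood at 10.40 against 5.57 on the next highest array, with Y-linked genes also present. On KO_antibiotic 3 the Y-linked genes Eif2s3y and Kdm5d stood at 4.78 and 4.52, against 7.06 and 5.85 on the next lowest arrays. Every Xist probe was undetected on KO_antibiotic 3, with levels from 4.47 to 4.71. Eif2s3y also separated the untreated groups, from 8.94 to 9.90 in WT_untreated and from 7.06 to 8.48 in KO_untreated. Kdm5d ran lower in KO_untreated with overlap, from 5.85 to 6.88 against 6.83 to 7.27 in WT_untreated. The cause was not tested.

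Probes of one gene passed with opposite signs for Ica1 (0.49 and -0.78) and Pcca (0.46 and -0.47) in untreated KO against WT mice, for Vmp1 (0.63 and -0.99) with antibiotics in WT and for H2ac20 (0.90 and -0.66) and Ptpre (0.60 and -0.38) with antibiotics in KO mice.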
